A study of Mus musculus with 8 samples.

How the data were processed

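Brown adipose tissue of mice aged 2 months was profiled in 2 genotypes, wild type (WT) and mice that lack the microRNA cluster of mir-193b and mir-365-1 (Null). The labels describe 6 mRNA-seq samples, 3 WT and 3 Null, and 2 microRNA-seq samples, 1 WT and 1 Null. Samples were assigned to groups by the genotype in the labels. Per the labels' protocols, mRNA libraries were made from poly(A) RNA with a TruSeq kit and sequenced on an Illumina instrument, and the microRNA libraries were made with an Illumina small RNA kit from RNA extracted with an miRNeasy kit. The mice were of mixed 129SV, FVB/N and C57BL/6 background.

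Per the submitters' processing notes, the tools used included CASAVA, TopHat, BWA, edgeR and DESeq, and the genome build was mm9. The role of each tool, its version, the gene annotation and any filters are not given in the sources used here. The authors deposited the mRNA data as FPKM, that is fragments scaled by transcript length and by mapped fragments, for 22552 genes, with 1 column per genotype per the file headers. The 3 libraries of a genotype were therefore pooled or averaged by the authors before deposit, and the sources do not say which. The combined values are called the WT pool and the Null pool. They carry no SD and no n, and the depth of the mRNA libraries is unknown. The columns sum to 508701 FPKM in WT and 590327 FPKM in Null. A value of 0 can be a failed estimate: 5796 genes were listed at 0 in WT and 6016 in Null, Scd1 and Hmgcs1 among them in both, and Fasn was listed at 0 in WT and at 1641 FPKM in Null. Gapdh, which every cell uses, was at 3.38 FPKM in WT and 0.463 FPKM in Null. Genes that share sequence with near-identical copies, such as haemoglobin genes, ribosomal protein genes and Gapdh, are uncertain for the same reason. Small RNA genes, recognised by symbols that start with Mir, Snor, Scarna, Rnu, Rny, Rpr or Rmrp, are shorter than the fragments of a poly(A) library, and 77 of the 172 with a mean of at least 1 FPKM were listed at 0 in 1 pool.

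The microRNA values are headed RPM, reads scaled to a library total, per the file headers and are treated as a signal deposited by the authors. The 386 listed microRNAs sum to 1559381 in WT and 1578515 in Null and so are above the total that the name RPM implies: the values are not shares of the reads assigned to microRNAs. Every value was a whole multiple of 1 step per library, 0.0438 in WT and 0.0411 in Null, with 100% of values within 0.01 step of a whole number. The steps imply 35611070 reads on the listed microRNAs in WT and 38435013 in Null. They also imply scaling totals of 22836670 reads in WT and 24348848 in Null, which are below these sums. The sums are therefore not a measure of library depth. Exact Poisson intervals for a level and exact Clopper-Pearson intervals for a ratio were computed at 95% from these implied reads. They cover counting error only, since PCR copies are not independent molecules and each genotype had 1 library. Some mature microRNAs share their reads, miR-199a-3p and miR-199b-3p for example, and miR-365-3p is the product of both mir-365-1 and mir-365-2. The authors' deposited table also gives the ratio of Null to WT and a p-value and adjusted p-value per microRNA. These p-values compare 2 libraries, not 2 groups of mice. The lowest mean RPM in the table is 5.10, so microRNAs below about that level were not analysed here.

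The design fixed before the data were examined was a linear model over 6 libraries with tests of gene lists. It could not be run on 1 column per genotype. Differences are therefore given as values, with no test between genotypes: log2((Null + 1)/(WT + 1)) of FPKM for the 11597 genes with a mean of at least 1 FPKM, counted as differing at 2-fold or more. This scale understates the change of low genes. For microRNAs the same ratio with a pseudocount of 1 RPM was used over the 323 with a mean of at least 10 RPM. A list of genes was described by its median log2 ratio and the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins (8 bins for microRNAs). A median outside the central 95% of the random lists is said to lie outside the random range. This describes these pools only, because genes of a list are expressed together and are not independent replicates, which makes percentiles too extreme. The 28 gene lists, with 547 of 557 entries in the table, and 12 microRNA lists were fixed before the data were examined, and 27 gene lists had at least 3 measured members. In a test on simulated data drawn over the 11597 genes, 6.48% of 540 unchanged lists lay outside the range, as did 94.4% of lists shifted by 0.5 and 100% of lists shifted by 1 on the log2 scale. The simulated values were independent and normal with an SD of 0.36, and list members were drawn at random. The 6.48% is therefore not a rate for real lists, whose genes are expressed together.

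The rule for named genes was fixed beforehand as the 10 genes per direction with the largest change past a test, up to 4 members of each list past the test or otherwise its 3 members with the highest expression, a set of 16 genes of brown fat and muscle, and the deleted, most changed and most abundant microRNAs. Without a test it was adapted after the table was seen. The 10 genes per direction are those with the largest log2 ratio at a mean of at least 1 FPKM, small RNA genes and genes listed at 0 left out, and list members are those that differed by 1.5-fold or more or had the highest FPKM. Some further list members are named as genes that differed little or ran against their list, and a few members that the rule would name are not reported here.

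Alternatives were a pseudocount of 0.1 FPKM or none, no filter on low values, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, and leaving out small RNA genes or genes listed at 0. For microRNAs they were a pseudocount of 10 RPM, a mean of at least 100 RPM and median-of-ratios scaling. Leaving out small RNA genes or genes listed at 0, and using no pseudocount, were chosen after seeing the data. So were 7 further lists: ribosomal protein genes, general genes with short mRNAs and with long mRNAs, and muscle fibre and respiratory chain genes divided the same way. Lengths were assigned from general knowledge of the genes, not measured. Gene order along the chromosome came from a RefSeq table of assembly GRCm38.p6, in which 20004 of the 22552 symbols were current names and 22343 were current or older names. Its build differs from mm9, so no coordinates are given. Seed sites of the deleted microRNAs were not analysed here because they need transcript sequences. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.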

Results

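Brown adipose tissue, the heat-producing fat of mice, was compared between WT mice and mice lacking mir-193b and mir-365-1 at 2 months of age. Small RNA sequencing covered 1 WT and 1 Null sample, with 35611070 and 38435013 reads implied on the 386 listed microRNAs. These sums exceed the scaling totals implied by the same values and are not a measure of library depth. The mRNA data covered 3 WT and 3 Null samples, combined by the authors into 1 FPKM value per genotype, here the WT pool and the Null pool. Neither assay therefore had replicates to compare, and no difference below has a replicate check. The depth of the mRNA libraries is unknown, and intervals for microRNAs cover counting error only.

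The first comparison asked whether the microRNAs of the cluster were missing from Null tissue. In WT brown fat miR-193b-3p was an abundant microRNA at 3705 RPM, with a 95% exact Poisson interval of 3680 to 3730. In the Null library it was at 11.5 RPM, which was 0.311% of WT with an exact Clopper-Pearson interval of 0.276% to 0.350%. Its partner strand miR-193b-5p was at 37.9 RPM in WT and 0.0821 RPM in Null, where 2 reads were implied, a ratio of 0.00217 (0.000262 to 0.00786). The strand specific to mir-365-1, miR-365-1-5p, was at 11.8 RPM in WT and 0.0821 RPM in Null, again 2 implied reads, a ratio of 0.00697 (0.000840 to 0.0254). The mature miR-365-3p can also be made from mir-365-2, a copy outside the deleted cluster. It remained at 798 RPM in Null against 1442 RPM in WT, a ratio of 0.553 (0.543 to 0.563).

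The relatives encoded elsewhere were present in both libraries. miR-193a-3p, which has the same seed as miR-193b-3p, was at 3857 RPM in WT and 4067 RPM in Null, a ratio of 1.05 (1.04 to 1.06). miR-193a-5p was at 27.3 and 31.5 RPM. miR-365-2-5p, the strand specific to the remaining copy, was at 9.37 RPM in WT and 17.9 RPM in Null, a ratio of 1.91 (1.62 to 2.26). Over all 323 microRNAs with a mean of at least 10 RPM the median log2 ratio was 0.17, and the miR-193a-3p ratio lay 0.10 below that median. The sums over all listed microRNAs differed less, at 1559381 in WT and 1578515 in Null. In the poly(A) table the gene entry Mir365-1 was at 41.0 FPKM in WT and listed at 0 in Null, Mir365-2 was at 48.4 and 7.90 FPKM, and Mir193b was listed at 0 in both, but entries of small RNA genes in that table were unreliable.

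**Figure D1:**
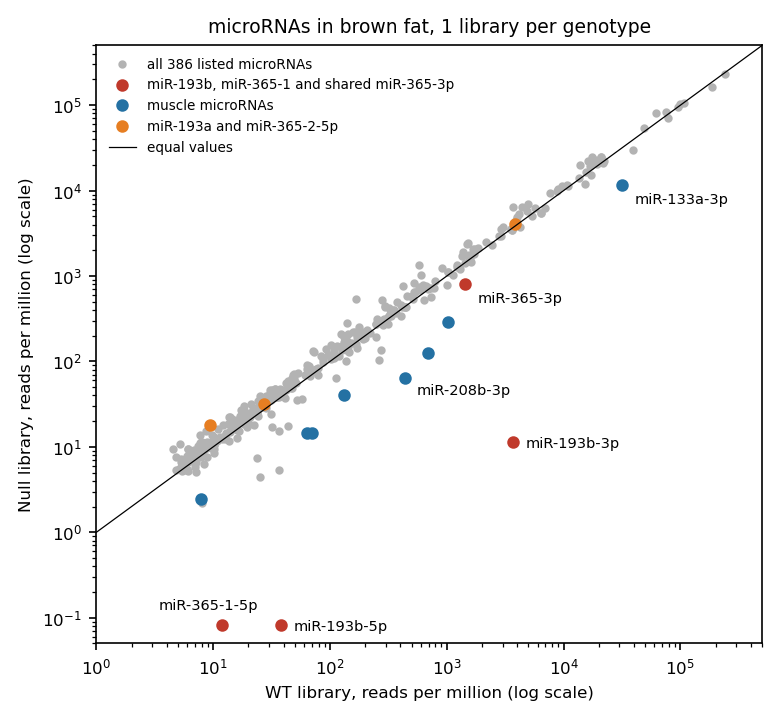
Each point is 1 of the 386 listed microRNAs, with its level in the WT library on the x axis and in the Null library on the y axis, both in RPM on log scales, and the line marks equal values. The strands of miR-193b and miR-365-1-5p lie far below the line, from 3705 to 11.5 RPM for miR-193b-3p, and the 8 muscle microRNAs, 1 of them under a mean of 10 RPM, also lie below it.

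Among other microRNAs, those of skeletal and cardiac muscle were the group that stood lowest in the Null library. All 7 measured members of the muscle list were lower by 1.5-fold or more, with a median log2 ratio of -2.03, which was -2.21 relative to all microRNAs and below all 10000 random lists. miR-133a-3p, the most abundant, was at 31477 RPM in WT and 11510 RPM in Null, a ratio of 0.366 (0.364 to 0.367). miR-1a-3p was at 1029 and 289 RPM, a ratio of 0.281, and miR-133b-3p at 689 and 127 RPM, a ratio of 0.184. miR-208b-3p and miR-499-5p, which lie within myosin heavy chain genes, had ratios of 0.147 and 0.211, and miR-206-3p had a ratio of 0.232.

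The rest of the microRNA profile differed less. Of the 323 microRNAs, 85.8% lay within 1.5-fold, 15 were lower in Null by 2-fold or more and 2 were higher. The higher ones were miR-455-3p, at 167 RPM in WT and 544 RPM in Null, a ratio of 3.27 (3.15 to 3.39), and miR-183-5p, at 581 and 1330 RPM, a ratio of 2.29 (2.24 to 2.34). Besides miR-193b and the muscle microRNAs, miR-205-5p (ratio 0.145), miR-122-5p (0.176), miR-200b-3p (0.309), miR-149-5p (0.393), miR-3096b-5p (0.394) and miR-3096a-5p (0.414) were lower. Relative to the median of all microRNAs the counts were 18 lower and 2 higher. The 7 immune microRNAs had a median log2 ratio of 0.60 at percentile 99.9, and 5 of them were higher relative to the median of all microRNAs, among them miR-142-5p (ratio 1.60), miR-146a-5p (1.97) and miR-146b-5p (1.86). miR-150-5p (ratio 1.03) and miR-155-5p (1.05) lay -0.13 and -0.10 from that median. Adipose-associated microRNAs had a median of 0.26 at percentile 97.6, and their most abundant member miR-378a-3p was at 188029 RPM in WT and 162708 RPM in Null. Blood microRNAs had a median of 0.29 at percentile 90.5, with miR-451a, abundant in red cells, at 3653 and 6343 RPM. By the authors' deposited table, 21 microRNAs had an adjusted p under 0.05, 20 of them lower and 1 higher in Null, in a test that compares these 2 libraries.

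The mRNA comparison asked which genes of brown fat differed when the cluster was missing. Most did not differ by much between the pools: 85.4% of the 11597 genes measured lay within 1.5-fold, and the median log2 ratio was 0.01. By 2-fold or more, 252 genes were higher in Null and 191 were lower. Without small RNA genes, 188 of 11425 genes were higher and 135 lower. Apart from small RNA genes and genes listed at 0, the largest difference upward was Prap1, a proline-rich secreted protein known from epithelia, at 1.19 FPKM in WT and 110 FPKM in Null, a log2 ratio of 5.67. Guca2b, which encodes uroguanylin, was at 0.196 and 7.32 FPKM, Apoa2 at 0.101 and 5.84 FPKM, and S100g, a calcium-binding protein, at 0.116 and 3.56 FPKM. Also among the 10 highest ratios were Gm9961 (1.41 and 14.7 FPKM), the haemoglobin gene Hbb-b1 (10.1 and 66.3 FPKM), 5730408K05Rik (0.810 and 7.14 FPKM), Angptl1 (0.935 and 7.15 FPKM), the neutrophil gene S100a9 (2.23 and 12.0 FPKM) and Rgs2, a regulator of G protein signalling (51.3 and 206 FPKM).

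Again apart from small RNA genes and genes listed at 0, Elovl3 had the largest difference downward with a pseudocount of 1 FPKM. This fatty acid elongase, typical of active brown fat, was at 88.3 FPKM in WT and 17.5 FPKM in Null, a log2 ratio of -2.27. Deptor, an inhibitor of mTOR, was at 62.2 and 16.1 FPKM, and Cish, an inhibitor of cytokine signalling, at 11.8 and 2.78 FPKM. The myosin heavy chain genes Myh2, Myh1 and Myh7 had log2 ratios of -1.86, -1.79 and -1.70. The pseudogene Pisd-ps1 (2.96 and 0.0504 FPKM), which was lowest with a pseudocount of 0.1 FPKM at -4.34 against -2.33 for Elovl3, Gm5506 (41.3 and 11.4 FPKM), Tlcd2 (19.1 and 5.11 FPKM) and Rims4 (9.56 and 2.32 FPKM) completed the 10 lowest ratios.

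Of 27 gene lists, 9 lay above and 9 below the random range, where 1.35 would be outside it by chance if genes of a list were independent. The ratios also differed between lists of general genes assigned short and long mRNAs, with lengths taken from general knowledge and not measured. General genes with short mRNAs had a median log2 ratio of 0.63, with 60 of 63 higher in Null, and general genes with long mRNAs had a median of -0.42, with 0 of 61 higher. These lists were drawn up after the values had been seen. The span from -0.42 to 0.63 between these 2 medians is given beside the lists below as a comparison. Lengths were not assigned to most genes of those lists, so a median inside the span does not show that length accounts for it.

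**Figure D2:**
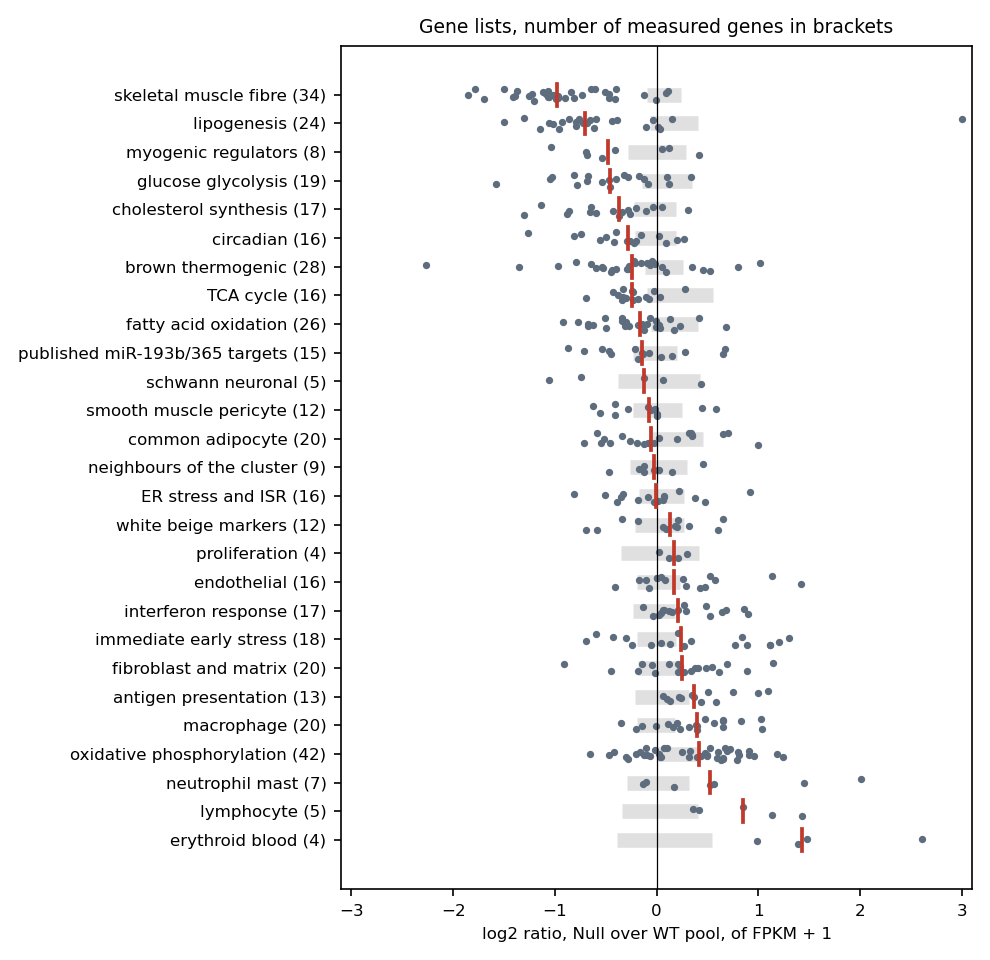
Each point is a measured gene, placed by its log2 ratio of FPKM + 1 in the Null over the WT pool on the x axis, with 1 line per gene list and the number of measured genes in brackets. Red bars mark the list medians, grey bars the central 95% of medians of 10000 random lists matched on expression, and Fasn, listed at 0 in WT, is drawn at the right edge of the lipogenesis line. Skeletal muscle fibre genes had the lowest median, -0.98, and erythroid genes the highest, 1.43.

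Several genes typical of brown fat were abundant in both pools. Ucp1, the uncoupling protein through which brown fat makes heat, was at 3016 FPKM in WT and 2487 FPKM in Null, a log2 ratio of -0.28. With quantile normalization the Ucp1 ratio was -0.79. Cidea was at 2615 and 2717 FPKM (0.06, and -0.39 with quantile normalization), Prdm16, a regulator of brown fat identity, at 6.91 and 6.58 FPKM (-0.06), and Ppargc1a, a coactivator of mitochondrial genes, at 15.5 and 13.2 FPKM (-0.21). Dio2, which activates thyroid hormone, was lower in Null at 18.6 and 9.05 FPKM (-0.97). The thermogenic list as a whole had a median of -0.25 at percentile 0.05, with 21 of 28 genes lower. By 1.5-fold or more, 6 were lower, including Elovl3, Acot11 (203 and 78.9 FPKM), Ppara (71.9 and 41.2 FPKM) and Dio2. The 2 that were higher were Cox7a1 (2634 and 5343 FPKM) and Cox8b (6407 and 11163 FPKM), short mRNAs of respiratory chain subunits. The median of this list lay between those of general long and short mRNAs.

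Genes shared by all fat cells had a median log2 ratio of -0.06 at percentile 3.18, inside the random range, with 9 of 20 higher and 11 lower. With quantile normalization it was -0.25 at percentile 2.76, also inside that range. The fatty acid carrier Fabp4 was the most abundant gene in both pools, at 27295 FPKM in WT and 34679 FPKM in Null (0.35). With quantile normalization its ratio was 0.00 by construction, since that setting gives the top gene of both pools the same value. Adipoq, which encodes adiponectin, was at 1163 and 1899 FPKM (0.71, and 0.37 with quantile normalization), and Cfd, which encodes adipsin, at 1334 and 2672 FPKM (1.00). The adipogenic factors Pparg, at 233 and 237 FPKM (0.03, and -0.17 with quantile normalization), and Cebpb, at 122 and 120 FPKM (-0.03, and -0.18 with quantile normalization), differed little. Markers of white and beige fat had a median of 0.13 at percentile 81.0, with Retn at 220 and 347 FPKM and Lep at 60.6 and 39.9 FPKM.

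Skeletal muscle fibre genes were lower in the Null pool, as were the muscle microRNAs in the Null microRNA library. Of 34 fibre genes 32 were lower and 25 were lower by 1.5-fold or more, with a median log2 ratio of -0.98 below all 10000 random lists. Besides the myosins, Actn2 was at 20.6 and 6.63 FPKM, skeletal actin Acta1 at 647 and 320 FPKM (-1.01), and muscle creatine kinase Ckm at 491 and 354 FPKM (-0.47). Fibre genes with short mRNAs had a median of -0.61, against 0.63 for general short mRNAs, and those with long mRNAs a median of -1.31, against -0.42 for general long mRNAs. The 2 fibre genes that were not lower were Mylpf (481 and 513 FPKM) and Myl1 (179 and 194 FPKM). Regulators of the myogenic programme had a median of -0.47 at percentile 0.1 over 8 measured genes, -0.06 from that of general long mRNAs, and of -0.16 over 19 genes with no filter on low values. Of the 8 genes, 3 were higher and 5 lower, with Mef2d (-1.04), Myf6 (-0.70) and Mef2a (-0.68) lowest. Myod1 (0.442 and 0.152 FPKM) and Myog (0.272 and 0.136 FPKM), which commit cells to muscle, were below the expression filter in both pools.

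Genes of fatty acid and triglyceride synthesis were lower in Null, with a median log2 ratio of -0.70 below all 10000 random lists. Of 24 genes 20 were lower, 16 of them by 1.5-fold or more. They included Gpam, the first enzyme of triglyceride synthesis (98.5 and 34.2 FPKM), Elovl6 (353 and 143 FPKM), the sterol-regulated Insig1 (268 and 121 FPKM) and Acss2, which makes acetyl-CoA (638 and 305 FPKM). Thrsp (6483 and 6622 FPKM) and Dgat2 (1068 and 1044 FPKM) differed little, and Fasn, listed at 0 in WT, counts among the 4 higher only through that entry. The median lay -0.29 from that of general long mRNAs. Genes of cholesterol synthesis had a median of -0.37 at percentile 0.05, with Lss (-0.88) and Fdps (-0.86) among the lower ones, close to the median of long mRNAs.

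Glycolysis genes had a median of -0.45, below all 10000 random lists and -0.04 from that of general long mRNAs. With quantile normalization it was -0.73, against -0.42 for general long mRNAs in that setting. In the list, Hk1 (-1.03), Pfkl (-0.82) and Hk2 (-0.79) were among the lower ones. Gapdh (-1.58) and Eno1 (-1.05) were lower still but at few FPKM, far under their usual abundance. Several glycolysis genes are also abundant in muscle fibres, whose own genes were lower by a median of -0.98, but a link between the lists was not tested. The citric acid cycle list had a median of -0.24 at percentile 0.31, with 14 of 16 genes lower and Ogdh (-0.70) lowest. Fatty acid oxidation genes had a median of -0.16 at percentile 0.27, with 19 of 26 lower, among them Acsl5 (-0.92) and Acsl1 (-0.77), and Etfb higher (0.68). Circadian clock genes had a median of -0.28 at percentile 0.65, with the repressors Bhlhe40 (-1.26), Bhlhe41 (-0.81) and Per1 (-0.75) lowest. These 3 medians lay between those of general long and short mRNAs. With quantile normalization the citric acid cycle median was -0.52 and the fatty acid oxidation median -0.43, both below the -0.42 of general long mRNAs in that setting. That setting also lowered the ratio of the abundant gene Ucp1, from -0.28 to -0.79. These lists and the glycolysis list were not matched on expression to the general long mRNAs, so these comparisons do not separate length from expression level.

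Respiratory chain genes were higher in Null as a list, but small and large subunits differed. The oxidative phosphorylation list had a median of 0.42 at percentile 98.4, with 30 of 42 genes higher. The 23 small subunits with short mRNAs had a median of 0.65, with Cox6c at 1525 and 3468 FPKM, although Cox5a (0.03), Sdhd (-0.11) and Atp5g1 (-0.09) were not higher to any extent. The 11 large subunits had a median of -0.20, with Sdha at 1189 and 756 FPKM and Atp5b at 3868 and 2794 FPKM, although Cyc1 (0.10) and Atp5c1 (0.07) were not lower. Ribosomal protein genes, which also have short mRNAs, had a median of 0.90, with 65 of 70 higher, such as Rps15 at 457 and 1002 FPKM. The median of the oxidative phosphorylation list was 0.08, at percentile 77.6, with quantile normalization, and 0.43 at percentile 97.1 with a mean of at least 5 FPKM, both inside the random range.

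**Figure D3:**
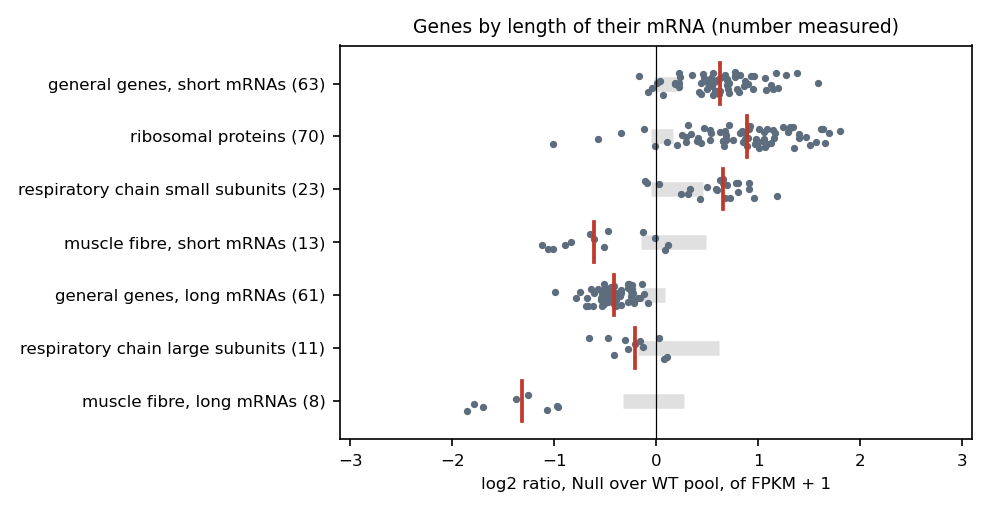
Each point is a measured gene, placed by its log2 ratio of FPKM + 1 in the Null over the WT pool on the x axis, with 1 line per group of genes with short or long mRNAs. Red bars are medians and grey bars the central 95% of medians of 10000 random lists. General short mRNAs (0.63), ribosomal proteins (0.90) and small respiratory chain subunits (0.65) lay to the right of 0, general long mRNAs (-0.42) to the left, and muscle fibre genes of either length (-0.61 and -1.31) further left than general genes of that length.

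As lists, markers of immune and blood cells were higher in the Null pool. Macrophage genes had a median log2 ratio of 0.39 at percentile 99.99, with 16 of 20 higher, including Aif1 (1.04), Fcer1g (1.03) and Tyrobp (0.83), while the receptor Csf1r was at 5.19 and 5.16 FPKM. The 5 measured lymphocyte genes were all higher, with a median of 0.85 and Cd52 at 11.8 and 33.6 FPKM. Neutrophil and mast cell genes had a median of 0.52 at percentile 99.91 over 7 genes, led by S100a9 (2.01) and S100a8 (1.44). All 13 antigen presentation genes were higher, with a median of 0.37 at percentile 98.8 and the proteasome subunits Psmb8 (1.09) and Psmb9 (1.00) highest. Of these, Cd74 (0.07) and H2-Ab1 (0.11) hardly differed. The 4 measured red cell genes had a median of 1.43, with Hba-a1 at 96.4 and 270 FPKM and Alas2, a haem synthesis enzyme, at 6.12 and 13.1 FPKM. By 1.5-fold or more, 6 of 20 macrophage, 3 of 5 lymphocyte, 2 of 7 neutrophil and mast cell and 3 of 13 antigen presentation genes were higher. So were all 4 red cell genes. Of the 5 list medians, those of macrophage, neutrophil and mast cell, and antigen presentation genes lay between those of general long and short mRNAs. The medians of lymphocyte and red cell genes lay above the 0.63 of general short mRNAs. With no filter on low values they were 0.39 over 24 lymphocyte genes and 0.59 over 8 red cell genes. With a pseudocount of 0.1 FPKM the neutrophil and mast cell median was 0.84, against 0.64 for general short mRNAs.

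Fibroblast and matrix genes had a median of 0.25 at percentile 99.2, with the collagens Col3a1 (61.6 and 137 FPKM) and Col1a2 (24.5 and 46.3 FPKM) highest and Pi16 lowest (17.5 and 8.82 FPKM). Some other long matrix mRNAs were not higher, among them Col5a1 (-0.02), Col4a1 (-0.05), Fbn1 (-0.19) and Fn1 (-0.45). Interferon-response genes had a median of 0.21 at percentile 98.7, with Bst2 (0.90) and Igtp (0.86) highest. Immediate early genes had a median of 0.24 at percentile 99.3, with Myc (1.30), Ier2 (1.20), Junb (1.12) and Jun (1.12) highest and Hsp90aa1 (-0.69) lowest. With no filter on low values the interferon median was 0.14 at percentile 95.1 and the immediate early median 0.17 at percentile 96.5, both inside the random range. At a mean of at least 5 FPKM the interferon median was 0.48 at percentile 99.93 over 11 genes.

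The last comparison asked whether genes reported in the literature as targets of the deleted microRNAs stood higher in the Null pool. It covers mRNA levels only and a partial loss. In the Null library miR-365-3p remained at 798 RPM against 1442 RPM in WT, and miR-193a-3p, with the seed of miR-193b-3p, was at 4067 RPM. Of 15 measured targets 5 were higher and 10 lower, and the median of -0.14 was inside the random range at percentile 12.3. Ywhaz (13.1 and 21.5 FPKM) and Plau (6.09 and 10.2 FPKM) were the 2 higher by 1.5-fold or more, and Hdac4 (2.04 and 0.658 FPKM) and Nf1 (6.22 and 3.41 FPKM) the 2 lower. Runx1t1, a reported target in brown fat cells, was below the expression filter at 0.291 and 0.227 FPKM. Cdon, a receptor of the myogenic programme, was at 3.36 and 2.00 FPKM (-0.54), and Igfbp5 at 22.7 and 19.9 FPKM (-0.18). The 9 measured genes of the neighbour list fixed beforehand had a median of -0.03, inside the random range, and none of these 9 differed by 1.5-fold or more. Gm9961 (2.70) and 2310015D24Rik (0.70) differed by that much. They are among the 20 measured genes nearest to mir-193b but were not in that list, and were picked out after their values were seen. Ercc4 (0.15) and Mkl2 (0.02) lie nearer to the cluster than Gm9961 on the same side.

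The remaining lists lay inside the random range at a mean of at least 1 FPKM. Endothelial genes had a median of 0.17 at percentile 92.5, with Cldn5 (1.42) and Egfl7 (1.13) highest and Pecam1 and Cdh5 at 0.04 and 0.01. At a mean of at least 5 FPKM the endothelial median was 0.26 at percentile 98.5, above the range. Smooth muscle and pericyte genes had a median of -0.07 at percentile 23.8, and the log2 ratio of Acta2 was under 0.01 in size. Schwann cell and neuronal genes had a median of -0.12 at percentile 21.6, with the myelin gene Mbp (-0.75) among the lower ones. At a mean of at least 5 FPKM their median was -0.43 at percentile 1.44 over 4 genes, below the range. The 4 measured proliferation genes had a median of 0.17 at percentile 78.1, and with no filter on low values 0.18 at percentile 99.6 over 19 genes, above the range. Genes of the endoplasmic reticulum stress response had a median of -0.01 at percentile 30.0, with Trib3 (0.91) highest and Fgf21 (-0.81) lowest. Of the epithelial list, 2 genes were measured, Krt10 (1.59 and 1.82 FPKM) and the milk protein gene Csn2 (0.973 and 2.02 FPKM), and with no filter its median was 0.12 at percentile 98.1 over 11 genes, above the range.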

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

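Under other pseudocounts, filters and scalings no list median outside the random range changed sign, nor did any ratio of 1.5-fold or more among the genes recomputed. Smaller ratios did: with quantile normalization Cidea went from 0.06 to -0.39 and Pparg from 0.03 to -0.17, and the list medians of neighbours (to 0.02 with no filter) and of stress response genes (to 0.04 at a mean of at least 5 FPKM) crossed 0. The causes were not tested. For the ratio of a single gene, only median-of-ratios scaling and quantile normalization could change the sign, since filters and pseudocounts cannot. Leaving out small RNA genes or genes listed at 0, and using no pseudocount, were chosen after seeing the data. Of the 47 values that alternatives gave for the main counts and levels, 42 stayed within 1.5 times of a count, 0.1 of the Ucp1 log2 ratio or the counting interval of a microRNA, and 5 moved further. With a pseudocount of 0.1 FPKM, 297 genes were lower by 2-fold or more, and 659 differed in total against 443. With quantile normalization the Ucp1 log2 ratio was -0.79. With median-of-ratios scaling miR-365-3p was at -1.04 against -0.85. At a mean of at least 100 RPM, where fewer microRNAs were counted, 8 differed by 2-fold or more, 6 of them lower. A further 435 values covered the genes with the largest ratios, the list medians, and the fixed set of genes other than Ucp1 that passed the expression filter. Of these, 374 moved by 0.1 or less and 61 by more. Settings that only drop genes leave the ratio of a single gene unchanged by construction. The 374, and the Ucp1 values among the 42, include such values and so overstate how stable the ratios are. The number of lists outside the random range was 17 or 18 in every setting. Not the same lists were involved: with no filter, proliferation and epithelial genes lay outside, and at a mean of at least 5 FPKM endothelial genes lay above and Schwann cell genes below.

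No paired analysis was possible because the mRNA columns combine the 3 samples of a genotype and carry no replicate number. The linear model, the replicate block, leaving out each replicate, sample weights, the fit without a trend, another threshold for the adjusted p, the gene set tests and the seed-site comparison were not run, since they need values per sample or transcript sequences. Without replicates no spread between mice is known, so differences in the mRNA data cannot be set against it. For microRNAs with few reads in Null the counting error was wide, as for miR-193b-5p (0.000262 to 0.00786), and variation between mice was not measured.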

Other observations

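The tests of explanations in this part were chosen after the gene ratios had been seen, as were the lists by mRNA length and the ribosomal protein list. The microRNA lists were fixed before the data were examined.

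Several microRNA families were level between the libraries once the overall median log2 ratio of 0.17 was taken into account. The let-7 family had a median of 0.14 over 19 members, the miR-17-92 family and its paralogs 0.18 over 13, and fibroblast-associated microRNAs 0.14 over 12. The endothelial strands miR-126-5p and miR-126-3p, with ratios of 1.30 and 1.26, lay 0.20 and 0.16 above the overall median on the log2 scale. The miR-30 family had a median of -0.02 at percentile 5.69, with 7 of 11 members lower in Null and 11 of 11 below the overall median, by a median of -0.19. Of the liver list, miR-122-5p was at 25.2 RPM in WT and 4.44 RPM in Null, while miR-192-5p was at 2936 and 2955 RPM. Within 1 precursor the strands could differ, as in mir-455, where miR-455-3p had a ratio of 3.27 (3.15 to 3.39) and miR-455-5p a ratio of 1.09 (1.06 to 1.13). Reads of the deleted strands that remained in Null were 0.311% of WT for miR-193b-3p, 0.217% for miR-193b-5p and 0.697% for miR-365-1-5p, with overlapping intervals of 0.276% to 0.350%, 0.0262% to 0.786% and 0.0840% to 2.54%.

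Skeletal muscle genes were lower in the Null pool by a median of -0.98, and 94.1% of the measured fibre list was lower. The trend with mRNA length is argued against as the whole cause: fibre genes with short mRNAs lay -1.24 from general genes with short mRNAs, although that trend alone would have put them higher in Null. Less skeletal muscle carried along with the Null dissections stays open: the share of fibre genes that were lower restates the pattern, and the 7 of 7 muscle microRNAs lower in a separate library do not separate this from a genotype effect. The abundant fibre genes Mylpf (0.09), Myl1 (0.12) and Pvalb (-0.01) were not clearly lower as plain ratios. All of them have short mRNAs and lay below the 0.63 of general short mRNAs. They therefore do not decide whether all fibre transcripts were lost equally. Of the 13 fibre genes with short mRNAs, 11 were lower and 2 higher. An effect of the genotype on muscle-like transcripts of brown fat stays open too, because each genotype is 1 pool. The direction of such an effect was not set beforehand.

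Ribosomal protein genes (median 0.90) and small respiratory chain subunits were higher in the Null pool. Reads shared with processed pseudogenes stay open: the 20 ribosomal protein genes with a mean of at least 100 FPKM had a median of 1.09, but the assignment of reads to genes and their copies was not measured. A trend of the ratios with mRNA length is a candidate explanation: general short mRNAs lay 1.05 above general long mRNAs. Small respiratory chain subunits lay 0.86 above large ones, which in part restates the pattern. Lengths were not measured, members such as Cox5a (0.03) and Cyc1 (0.10) departed from the trend, and its origin was not tested, and an effect of the genotype on these genes stays open.

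Lipid synthesis genes were lower in the Null pool, with a median of -0.70. Whether the same trend with length contributes stays open, since lengths were not assigned to these genes and the outcome depended on the setting. In the main setting their median lay -0.29 from that of general long mRNAs, between the limits set for and against the trend. The limit against it, -0.3, was passed at a mean of at least 5 FPKM (-0.302) and with quantile normalization (-0.48). It was not passed with a pseudocount of 0.1 FPKM (-0.27) or median-of-ratios scaling (-0.29). A length effect and a genotype effect cannot be told apart for these genes, because lengths were not measured and each genotype is 1 pool. Thrsp and Dgat2, which differed little, show that the list did not move as 1 block.

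The first 727 genes of the FPKM table were ordered by the ratio of Null to WT, with 331 genes higher and 396 lower, and the rest by name. The criterion for this block is not given in the sources used here, and 747 other genes with a mean of at least 1 FPKM reached its smallest fold of 1.63. Small RNA genes and genes listed at 0 were left out of the 747. The block held 22 of the 34 muscle fibre genes and 38 ribosomal protein genes, all 38 higher. Prap1, in this block, had the largest ratio of the 20 genes named for their ratios, 92.9-fold on plain FPKM. Of the 20 measured genes nearest to mir-193b in RefSeq order, 10 on each side, the median size of the log2 ratio was 0.20, at percentile 28.25 of random lists. Gm9961 (1.41 and 14.7 FPKM, log2 ratio 2.70) and 2310015D24Rik (1.36 and 2.82 FPKM, log2 ratio 0.70), singled out among these after their values were seen, differed most.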
